A study of Mus musculus with 12 samples.

How the data were processed

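Polyadenylated RNA of immortalised mouse macrophages was sequenced in 12 libraries, 1 per labelled sample. Per the labels, the groups are WT mock (n = 2), WT Candida (n = 4), IRE1-null mock (n = 2) and IRE1-null Candida (n = 4), with Candida albicans for 4 h. The deposited names of the 2 replicate 4 libraries also hold the word mock, while their labels say Candida, and they were used as labelled and left out together as an alternative. The 1 library labelled IRE1-null mock replicate 2 was used as labelled and is named by its label throughout.

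Per the submitters' processing notes, the authors used FastQC, cutadapt, kallisto and DESeq2, with no versions, parameters or genome build given in the sources used here. Each library has a table with 1 line per RefSeq transcript (130329 transcripts). Per the file headers, the deposited estimated counts are kallisto's expected counts per transcript and are not normalised, and 24.9% of them are not whole numbers. The deposited TPM values are from kallisto, scaled to transcript length and library total. The deposited length and effective length columns are other values, in bases. Results of the authors' DESeq2 run are not used here.

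Transcripts were matched to genes by accession with the GRCm38.p6 RefSeq table: 106820 (82%) matched, 70976 of them with the same version, giving 35556 genes. Of 23509 transcripts without a match 23440 were predicted models, and they held 3.2% to 6.7% of the counts of a library. Estimated counts were summed per gene and rounded. The files list 0 mitochondrial transcripts, and the sequence of Candida albicans is not analysed here. Totals per library were 17.7 M to 25.9 M estimated counts. A count of 0 is read as fewer than 3 counts, and a fold change against a group of 0 counts is given as at least the ratio to 3 counts over that group.

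Tests used edgeR 4.0.16 in R 4.3.3: filterByExpr with the 4 groups left 13410 genes, TMM factors were 0.957 to 1.035, and a quasi-likelihood fit with robust dispersion and a model of the 4 groups gave 5 comparisons. These are Candida against mock in each genotype, IRE1-null against WT in mock and in Candida, and the interaction. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called. Spread is pooled over all groups, so in groups of 2, or of 1 where a library is left out, a sample is assumed to vary like the other groups. DESeq2 1.42.0 was the second tool. Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated and with fry. Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 did the rest.

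The lists were IRE1-XBP1 targets, RIDD substrates, ATF6-type ER chaperones, the PERK-ATF4 stress response, cytokines and chemokines, NF-kB pathway and feedback, immediate early genes, the type I interferon response, fungal recognition and C-type lectin signalling, lysosome and phagosome, NADPH oxidase, the NRF2 oxidative stress response, inflammasome and cell death, glycolysis and hypoxia response, cholesterol synthesis and uptake, cholesterol efflux (LXR targets), S phase, G2/M phase, p53 targets, macrophage identity and MHC class II presentation. Markers of neutrophils, dendritic cells, fibroblasts and lymphocytes, and mitochondrial and ribosomal protein transcripts as measures of RNA quality, made the others. Members and the rule for naming genes were written before the data were examined. The rule takes, per comparison, the 10 largest positive and 10 largest negative called changes with a mean log2 CPM of at least 2 and groups that do not overlap, leaving out predicted symbols, up to 4 members of each list with the smallest p, and Ern1, Xbp1, Dnajb9, Bloc1s1, Hspa5, Ddit3, Tnf, Il1b, Il6, Il10 and Cxcl2. The text leaves some of these genes out in order of rank, and a few further results are not reported here.

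Shares of spliced Xbp1 are estimated counts of the shorter isoform (2238 against 2264 nucleotides, 26 apart) over all Xbp1 counts, with exact Clopper-Pearson 95% intervals and a two-sided exact permutation test over libraries, run again with swaps only within pairs of the same number. For chromosomes, genes with a mean log2 CPM of at least 1 and a position in GRCm38.p6 were used, and each pair of same-number libraries gave a median log2 ratio. A table of GC content covered 97.7% of these genes.

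Whether numbers mark pairs was checked by correlating residuals from group means. Candida libraries of the same number correlated across genotypes at 0.34, 0.35, 0.17 and 0.16, so numbers were read as pairs. The mock libraries give 1 value, 0.21, since residuals in a group of 2 mirror each other. Library numbers in the titles (1 to 4, 13 to 16 and 25 to 28) were read as 3 runs, which the sources used here do not state. In run 3, numbers 3 and 4 were not separable (WT 3 with IRE1-null 4 at 0.20, WT 4 with IRE1-null 3 at 0.16). WT mock with WT Candida gave 0.37 and 0.12 and IRE1-null mock with IRE1-null Candida 0.21 and 0.09, the second of which holds the library labelled IRE1-null mock replicate 2. Results with replicate number as a block are printed where they change a call or move a count more than 1.5 times.

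The edgeR fit was tested on simulated data with these library sizes and group sizes, in which 200 genes were changed by 2-fold or 4-fold. The simulation held no run difference and no infected library without a response. Of the genes called, 1 of 93 in the WT comparison, 1 of 81 in the IRE1-null comparison, 5 of 75 in mock, 8 of 129 under Candida and 3 of 45 in the interaction were false. Alternatives were DESeq2 size factors, the DESeq2 Wald test, no filter on low counts, a length offset, both replicate 4 libraries left out, each library left out, replicate number or run as a block, the 2 compared groups alone, the other list tests and, for the agreement of responses, the called genes alone. Alternatives added after the data were seen leave out both Candida libraries numbered 2, alone or with the library labelled IRE1-null mock replicate 2, keep transcripts without a match, vary the spliced share, and add a block to the correlation of responses.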

Results

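The libraries come from mouse bone-marrow-derived macrophages immortalised with J2 virus, wild type (WT) or IRE1-null per the labels, either mock-treated or infected with Candida albicans for 4 h. IRE1, encoded by Ern1, is an endoplasmic reticulum (ER) stress sensor whose endoribonuclease removes an intron from Xbp1 mRNA, and the spliced mRNA encodes the transcription factor XBP1s. The design asks which parts of the macrophage response to the fungus need IRE1. There are 2 mock and 4 Candida libraries per genotype, 12 in all, with 17.7 M to 25.9 M estimated counts each, and 13410 genes entered the tests. Library numbers in the titles were read as 3 runs, which the sources used here do not state. On that reading run 1 holds replicate 1 of all 4 groups, run 2 replicate 2 of all 4 groups, and run 3 replicates 3 and 4 of the Candida groups and no mock library. The sources used here do not state whether replicates are separate cultures, so p-values measure the spread between libraries, which may be technical. Cdkn2a had 0 counts in all 6 WT libraries, and genotype differences followed chromosomes 2 and 13. The genotypes may therefore differ as cell lines in more than IRE1. Libraries replicate the lines used, and no p-value between genotypes separates loss of IRE1 from line. Gene values are counts scaled to library size (CPM), given as mean ± SD, and SE is the standard error of a log2 fold change. The library labelled IRE1-null mock replicate 2 lies between the genotypes: of 522 genes that differ, 94.4% are 20% to 80% of the way from IRE1-null to WT, and comparisons that draw on it name it.

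The targeted gene was not lost as a transcript. Ern1 was 3.89 and 2.11 CPM in the WT mock libraries and 4.63, 1.32, 1.95 and 2.26 CPM in WT Candida replicates 1 to 4. It was 20.7 CPM in IRE1-null mock replicate 1, 7.74 CPM in the library labelled IRE1-null mock replicate 2, and 21.5, 16.4, 18.2 and 14.6 CPM in IRE1-null Candida replicates 1 to 4. Under Candida Ern1 was higher in IRE1-null cells (17.7 ± 2.92 against 2.54 ± 1.45 CPM, n = 4 and n = 4, log2 fold change 2.80, SE 0.43, edgeR adjusted p = 0.00145). In mock cells the difference was 2.24 (SE 0.60, edgeR adjusted p = 0.108, n = 2 and n = 2), and it passed with replicate number as a block (edgeR adjusted p = 0.0076) or without the library labelled IRE1-null mock replicate 2 (2.74, edgeR adjusted p = 0.0404). Ern1 did not pass between Candida and mock in WT (-0.25, edgeR adjusted p = 0.971) or IRE1-null cells (0.32, edgeR adjusted p = 0.882). A sum over transcripts does not show a deletion of part of the gene, so Ern1 counts do not test whether a working protein is made.

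Splicing of Xbp1 gives a readout of that activity. Spliced Xbp1 made up 8.26% (95% exact interval 7.07 to 9.53), 0.56% (0.29 to 1.04), 3.62% (2.85 to 4.5) and 3.27% (2.51 to 4.14) of Xbp1 estimated counts in WT Candida replicates 1 to 4. The mock WT libraries held 1.72% (1.17 to 2.41) and 0% (3 counts would be 0.155%). In IRE1-null cells it was 0% in Candida replicates 1, 2 and 3 (3 counts would be 0.168%, 0.15% and 0.129%) and 0.28% (0.13 to 0.57) in replicate 4. IRE1-null mock replicate 1 held 0.43% (0.16 to 0.84), and the library labelled IRE1-null mock replicate 2 held 0% (3 counts would be 0.124%). The intervals carry counting error only. Under Candida the IRE1-null mean was lower by 3.86 percentage points (exact two-sided permutation p = 0.0286, the smallest possible with 4 against 4, n = 4 and n = 4). With genotypes swapped only within pairs of the same replicate number, the exact two-sided permutation p was 0.125 (n = 4 pairs), the smallest possible for 4 pairs, so the call is lost on that reading of the numbers. On TPM the difference was -3.91 points. The exact permutation p was 0.0571 (n = 3 against 4) without any single IRE1-null Candida library and 0.0286, the smallest possible at these sizes, without any single WT Candida library. Differences over all single omissions were -4.98 to -2.41 points. This measure was chosen after the files had been opened, and it is a kallisto estimate between isoforms of 2264 and 2238 nucleotides. Total Xbp1 did not differ between genotypes under Candida (98.4 ± 13.5 against 107 ± 11.7 CPM, n = 4 and n = 4, log2 fold change 0.12, edgeR adjusted p = 0.682) or in mock (0.06, edgeR adjusted p = 0.974). Of XBP1s-linked genes, Dnajb9, an ER co-chaperone, differed by -0.43 under Candida (edgeR adjusted p = 0.427), and Hspa5, the chaperone BiP on chromosome 2, by -0.29 (edgeR adjusted p = 0.618, or 0.0094 with replicate number as a block).

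**Figure D1:**
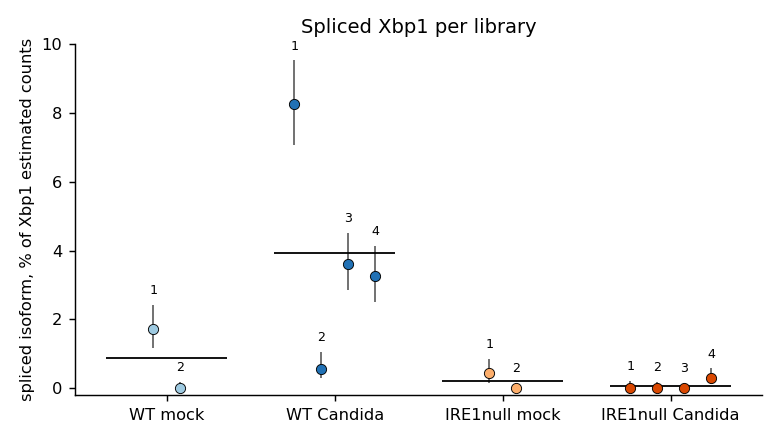
Spliced Xbp1 isoform as a percentage of Xbp1 estimated counts (y axis) in each library (points, numbered by replicate) of the 4 groups (x axis). WT Candida libraries hold 8.26%, 0.56%, 3.62% and 3.27%, and 3 of 4 IRE1-null Candida libraries hold 0%.

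In infected WT macrophages inflammatory gene lists were called higher by camera at a preset correlation, and no single gene passed the test. The list calls were lost once the correlation was estimated: glycolysis had adjusted p = 0.801 with an estimated correlation, and each of the other 5 adjusted p = 0.752 with an estimated correlation. At the preset correlation 5 lists rose: NF-kB pathway and feedback (22 of 24 members with a positive change), cytokines and chemokines (17 of 19), immediate early genes (18 of 20), the PERK-ATF4 stress response (17 of 20) and glycolysis and hypoxia response (23 of 26). Ribosomal proteins fell as a group (0 of 14 positive, median -0.13). Of NF-kB genes, Tnfaip3, a feedback inhibitor, was 1.11 ± 0.257 CPM in mock (n = 2) and 18.7 ± 14.3 CPM in Candida (n = 4). Ier3, which restrains cell death, went from 5.32 ± 0.62 to 34.2 ± 22.5 CPM. Of chemokines that draw monocytes, Ccl2 was 8.51 ± 1.31 CPM in mock and 49.9 ± 28.8 CPM in Candida (log2 fold change 2.55, SE 0.74). Ccl7 was 1.23 ± 0.587 and 13.5 ± 8.58 CPM (3.46, SE 0.98). The cytokine Tnf was 2.0 ± 0.117 and 19.3 ± 15.6 CPM (3.26, SE 1.17). The neutrophil chemokine Cxcl2 was 0.048 ± 0.0679 and 5.79 ± 6.21 CPM, and the cytokine Il1b 1.54 ± 1.01 and 3.97 ± 4.44 CPM. Immediate early genes held Jun, an AP-1 subunit (29.9 ± 6.26 and 136 ± 80.4 CPM, 2.18, SE 0.62), and Dusp4, a kinase phosphatase (1.85 ± 0.102 and 30.5 ± 23.6 CPM). Stress-response transcription factors Atf4 (150 ± 0.791 and 362 ± 142 CPM, 1.27, SE 0.38) and Atf3 (82.1 ± 17.8 and 385 ± 237 CPM) stood higher too. So did the glycolysis regulator Pfkfb3 (10.7 ± 4.71 and 35.7 ± 13.6 CPM) and the vasoactive peptide gene Adm (0.559 ± 0.0921 and 15.3 ± 14.2 CPM). The pattern receptor Tlr2 was 59.0 ± 1.86 and 273 ± 219 CPM, and the haem-degrading enzyme gene Hmox1 118 ± 17.6 and 299 ± 172 CPM. None of these genes passed singly (edgeR adjusted p = 0.735, or 0.736 for Hmox1 and 0.908 for Il1b). The ER stress genes Ddit3 (0.51, edgeR adjusted p = 0.743), Hspa5 (0.15, edgeR adjusted p = 0.974) and Dnajb9 (0.59, edgeR adjusted p = 0.826), and Xbp1 (0.01, edgeR adjusted p = 1), did not pass.

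The WT changes were carried by 3 of the 4 infected libraries. Ccl2 was 52.0, 66.3 and 72.7 CPM in Candida replicates 1, 3 and 4 but 8.62 CPM in replicate 2, against 9.43 and 7.58 CPM in mock. Atf4 was 404 to 456 CPM in replicates 1, 3 and 4, 151 CPM in replicate 2 and 149 and 150 CPM in mock. The 63 tested genes of the cytokine, NF-kB and immediate early lists averaged 1.10 log2 units above the same-run mock library in run 1 and -0.11 in run 2. Within run 1 and run 2 the Candida minus mock differences were 0.79 and 0.22 for the NF-kB list, 1.24 and -0.46 for cytokines, 1.35 and -0.17 for immediate early genes, 0.69 and -0.04 for PERK-ATF4, 0.55 and -0.03 for glycolysis and -0.18 and 0.02 for ribosomal proteins. edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 of 13410 genes (894 at unadjusted p under 0.05, with 670 expected by chance; smallest adjusted p = 0.389), and DESeq2's Wald test called 36 (31 higher, 5 lower), among them Ccl2, Tnfaip3, Ier3, Jun and Pfkfb3. Without the 2 Candida libraries numbered 2, a setting chosen because they lacked the response, which leaves 1 same-run Candida and mock pair per genotype, edgeR called 200 genes (182 higher, 18 lower), with Ccl2 at 2.89 (edgeR adjusted p = 0.00082), Atf4 at 1.52 (0.00134), Jun at 2.52 (0.00197) and Tnf at 3.64 (0.0132). Leaving out single libraries gave 3 (WT mock 1), 8 (WT mock 2), 6 (WT Candida 2, with Jun at 2.50, edgeR adjusted p = 0.0112) and 2 (WT Candida 4) genes. In the self-test for this comparison 16% of 2-fold and 76% of 4-fold changes were recovered. It drew the changed genes at random and let all libraries of a group respond alike. Larger changes also fell short of the threshold here, such as Tnfaip3 at 4.06 and Adm at 4.76 on the log2 scale.

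By camera with a preset correlation the WT lists reached adjusted p = 8.12e-06 (NF-kB), 0.000163 (cytokines), 0.000347 (immediate early), 0.000762 (PERK-ATF4), 0.000932 (glycolysis) and 0.0286 (ribosomal proteins). fry, which asks whether the genes of a list change at all and not whether they change more than other genes, called none of them (adjusted p 0.547 to 0.634). Adjusted over each list alone, 2 cytokine genes, Ccl7 and Ccl2, passed, and none of the other 5 lists held a called gene. With replicate number as a block the cytokine list (adjusted p = 0.103) and glycolysis list (adjusted p = 0.552) were not called, and the type I interferon list was lower (adjusted p = 0.00244 against 0.0636; unblocked, adjusted p = 0.84 with an estimated correlation). Without WT mock 2 PERK-ATF4 (adjusted p = 0.31) and glycolysis (adjusted p = 0.45) lost the call. Ribosomal proteins lost it without WT mock 1, WT mock 2, WT Candida 1 or WT Candida 3 (adjusted p = 0.248, 0.145, 0.114 and 0.0861). Without both replicate 4 libraries ribosomal proteins lost the call (camera adjusted p = 0.0505) and the type I interferon list was called lower (0.03). With all libraries the other lists were not called (adjusted p 0.0636 to 0.791). Among them were IRE1-XBP1 targets (0.77), RIDD substrates (0.791), ATF6-type ER chaperones (0.521) and lysosome and phagosome (0.497).

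In IRE1-null macrophages the same 5 inflammatory and stress lists were called higher by camera at a preset correlation, and interferon and lipid lists were called as well. None of the 8 was called once the correlation was estimated: glycolysis and interferon had adjusted p = 0.709 with an estimated correlation, cholesterol synthesis adjusted p = 0.719 with an estimated correlation, and each of the other 5 adjusted p = 0.662 with an estimated correlation. The NF-kB list (20 of 24 positive, median 0.92), cytokines (17 of 19, 2.10), immediate early genes (18 of 20, 1.48), PERK-ATF4 (17 of 20, 0.48) and glycolysis (23 of 26, 0.49) rose. The type I interferon response (23 of 27 positive, median 0.76) and cholesterol synthesis and uptake (15 of 21, 0.31) also rose, while cholesterol efflux genes driven by LXR fell (1 of 8 positive, median -1.0). The interaction, which tests a difference from WT, did not call cholesterol synthesis (camera adjusted p = 0.217) or LXR targets (0.539). Without both Candida libraries numbered 2 it called cholesterol synthesis higher in the IRE1-null response (camera adjusted p = 0.0105). With all libraries that list had adjusted p = 0.972 with an estimated correlation. All directions draw on the library labelled IRE1-null mock replicate 2 as 1 of 2 mock libraries. Single chemokine genes stood higher without passing: Cxcl10, an interferon-inducible chemokine, was 6.36 ± 0.831 CPM in mock (n = 2) and 34.5 ± 16.9 CPM in Candida (n = 4, log2 fold change 2.44, SE 0.63, edgeR adjusted p = 0.38). Ccl3 was 18.9 ± 3.61 and 111 ± 53.7 CPM (2.55, edgeR adjusted p = 0.489). Tnf was 7.92 ± 3.33 and 53.9 ± 34.3 CPM (2.77, edgeR adjusted p = 0.518). Cxcl2 was 0.61 ± 0.304 and 11.3 ± 10.2 CPM, and Il1b 0.677 ± 0.12 and 1.65 ± 1.78 CPM. Egr1, an early growth-response factor, was 4.37 ± 1.44 and 84.8 ± 61.5 CPM (4.29, SE 1.16, edgeR adjusted p = 0.427). Ier3 was 7.13 ± 0.577 and 37.4 ± 20.4 CPM and Maff, a small AP-1-related factor, 6.02 ± 1.26 and 28.4 ± 16.1 CPM. Tnip1, an NF-kB inhibitor, was 65.2 ± 0.148 and 115 ± 28.5 CPM, and Mthfd2, an ATF4-driven folate enzyme, 120 ± 3.61 and 208 ± 35.9 CPM. Tlr2 was 58.1 ± 1.59 and 230 ± 112 CPM, and Hmox1 214 ± 6.97 and 607 ± 305 CPM. None of these passed (edgeR adjusted p = 0.518 for Ier3, Maff, Mthfd2, Tlr2 and Hmox1, 0.454 for Tnip1, 0.552 for Cxcl2 and 0.814 for Il1b). Ddit3 (0.71, edgeR adjusted p = 0.518), Hspa5 (0.30, edgeR adjusted p = 0.826), Dnajb9 (0.73, edgeR adjusted p = 0.575) and Xbp1 (0.07, edgeR adjusted p = 0.927) did not pass.

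In IRE1-null cells too, infected replicate 2 sat apart from the other infected libraries. Tnf was 49.4, 74.4 and 84.3 CPM in Candida replicates 1, 3 and 4 and 7.40 CPM in replicate 2, against 10.3 CPM in mock replicate 1 and 5.57 CPM in the library labelled IRE1-null mock replicate 2. The 63 inflammatory genes averaged 1.24 above mock in run 1 and 0.05 in run 2. All run 2 differences here take the library labelled IRE1-null mock replicate 2 as their mock. Within run 1 and run 2 the differences were 0.96 and -0.10 for NF-kB, 1.30 and 0.24 for cytokines, 1.53 and 0.05 for immediate early genes, 0.90 and -0.03 for PERK-ATF4 and 0.53 and -0.16 for glycolysis. They were -0.36 and 0.37 for interferon genes, 0.30 and 0.01 for cholesterol synthesis and -0.70 and -0.83 for LXR targets. edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 of 13410 genes (1210 at unadjusted p under 0.05, with 670 expected by chance; smallest adjusted p = 0.0527), against 97 by DESeq2's Wald test (21 higher, 76 lower). Without the 2 Candida libraries numbered 2 edgeR called 166 genes (115 higher, 51 lower), with Egr1 at 4.68 (edgeR adjusted p = 0.00288), Cxcl10 at 2.72 (0.0121), Ccl3 at 2.86 (0.0162) and Tnf at 3.14 (0.0204). That count was 6 when the library labelled IRE1-null mock replicate 2 was left out as well. Leaving out IRE1-null mock 1 gave 69 genes (2 higher, 67 lower), with the library labelled IRE1-null mock replicate 2 as the only mock, and leaving out IRE1-null Candida 2 gave 1. If the library labelled IRE1-null mock replicate 2 holds RNA of both lines, genes of WT cells would read as lower in these counts. Outside it, 9 genes were above 2 CPM in every WT library with at most 3 counts over the IRE1-null libraries. In it they were at 2.53 to 54.51 CPM on library totals alone. How many of the calls this accounts for was not tested. The self-test for this comparison recovered 13% of 2-fold and 67% of 4-fold changes.

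camera adjusted p in IRE1-null cells was 5.73e-05 for cytokines, immediate early genes and PERK-ATF4, 6.24e-05 for NF-kB, 0.00152 for glycolysis, 0.0167 for interferon and for cholesterol synthesis and 0.0278 for LXR targets. fry called LXR targets alone (adjusted p = 0.00806). Adjusted over each list alone, 2 cytokine genes, Cxcl10 and Ccl3, passed upward, and 1 interferon gene, Ifit2, passed downward. In the inflammasome and cell death list, which was not called, the pro-death gene Bcl2l11 on chromosome 2 also passed downward (-0.57, edgeR adjusted p = 0.403 over all genes). Ifit2, which restrains translation of viral RNA, had 0 counts in all 8 Candida libraries and 0.698 and 2.01 CPM in the IRE1-null mock libraries, the second being the library labelled IRE1-null mock replicate 2. The interferon list was not called with replicate number as a block (adjusted p = 0.232), without IRE1-null mock 1 (0.273), or without IRE1-null Candida 2, 3 or 4 (0.0714, 0.129 and 0.0915). Nor was it called without both Candida libraries numbered 2 (0.135), without these and the library labelled IRE1-null mock replicate 2 (0.0612), or without both replicate 4 libraries (0.0734). Cholesterol synthesis lost its call without the library labelled IRE1-null mock replicate 2 (adjusted p = 0.567) or without Candida 1, 3 or 4 (0.0646, 0.056 and 0.0613) or both replicate 4 libraries (0.0734), and LXR targets without that mock library (0.122) or Candida 1 (0.0646). Glycolysis lost it with the block (adjusted p = 0.232) and without the library labelled IRE1-null mock replicate 2 (adjusted p = 0.1). The other lists were not called (adjusted p 0.118 to 0.939), among them IRE1-XBP1 targets (0.118), ATF6-type ER chaperones (0.169) and RIDD substrates (0.939).

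**Figure D2:**
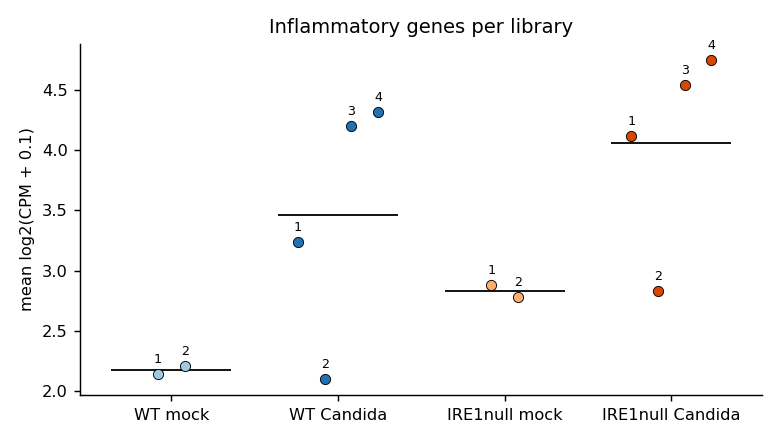
Mean log2(CPM + 0.1) of 63 genes of the cytokine, NF-kB and immediate early lists (y axis) in each library (points, numbered by replicate) of the 4 groups (x axis). Candida replicates 1, 3 and 4 stand above mock in both genotypes (WT 3.24, 4.20 and 4.32 against 2.14 and 2.21), while replicate 2 is at 2.10 in WT and 2.83 in IRE1-null cells, where 1 mock point is the library labelled IRE1-null mock replicate 2.

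Between genotypes in mock cells, interferon-stimulated genes were higher in IRE1-null macrophages, and some genes had 0 counts in the WT mock libraries. Line and loss of IRE1 cannot be told apart in this comparison. All directions here draw on the library labelled IRE1-null mock replicate 2 as 1 of 2 IRE1-null libraries. Of the type I interferon list, 27 of 27 genes had a positive difference and 5 were called (median 2.61, camera adjusted p = 7.75e-16; adjusted p = 0.216 with an estimated correlation). Oas1a, an antiviral RNA sensor, went from 24.5 ± 4.63 to 97.8 ± 5.67 CPM (n = 2 and n = 2, log2 fold change 2.0, SE 0.24, edgeR adjusted p = 0.00209). Irf7, the interferon-amplifying factor, went from 2.26 ± 0.141 to 24.4 ± 6.70 CPM (3.43, edgeR adjusted p = 0.0133). Cmpk2 and Usp18, interferon-induced enzymes, went from 0.0549 ± 0.0776 to 8.26 ± 3.16 CPM (edgeR adjusted p = 0.011) and from 0.072 ± 0.102 to 9.66 ± 3.70 CPM (edgeR adjusted p = 0.0122). The 4 tested of 7 MHC class II genes were higher as a group (3 positive, camera adjusted p = 0.00442; adjusted p = 0.216 with an estimated correlation), with the invariant chain Cd74 at 68.5 ± 44.5 and 336 ± 85.7 CPM (2.29, edgeR adjusted p = 0.0302). Class II chain genes themselves were near 0. H2-Aa and H2-Ab1, below the filter, were at 0 to 0.237 CPM over the 12 libraries, and H2-Eb1 was 0.598 CPM in IRE1-null mock. Arap3, a GTPase regulator, was at least 1050-fold higher (0 in WT, 80.5 ± 48.3 CPM in IRE1-null; 115 CPM in replicate 1 and 46.3 CPM in the library labelled IRE1-null mock replicate 2), though WT Candida libraries held 3.76 ± 2.42 CPM (n = 4). Ptgr1, a prostaglandin reductase, was at least 414-fold (0 and 31.8 ± 18 CPM) and the membrane protein gene Tmem37 at least 273-fold (0 and 20.9 ± 8.61 CPM). Of the 5 lower genes, the Golgi regulator Ric1 (-1.84, edgeR adjusted p = 0.0433), the peptidase Anpep (-1.40, edgeR adjusted p = 0.0066), the collagen hydroxylase Plod1 (-1.34, edgeR adjusted p = 0.0282) and the polyol enzyme Sord on chromosome 2 (-0.71, edgeR adjusted p = 0.0343) are known genes. The lower gene Gm2026 (-2.57, edgeR adjusted p = 0.0292) falls outside the naming rule and was chosen after its values were seen. IRE1-XBP1 targets were lower as a group, by little (28 of 32 lower, median -0.20, camera adjusted p = 0.00803; adjusted p = 0.335 with an estimated correlation), with no single call. Against them Edem1, an ER mannosidase-like degradation factor, was 150 ± 20.5 and 270 ± 42.7 CPM (0.85, edgeR adjusted p = 0.0556, or 0.00196 with replicate number as a block). Fcer1g, an adaptor of C-type lectin receptors, was higher (0.93, edgeR adjusted p = 0.0375). Tnf (1.98, edgeR adjusted p = 0.667), Dnajb9 (-0.57, edgeR adjusted p = 0.744) and Hspa5 (-0.45, edgeR adjusted p = 0.815, or 0.026 with the block) did not pass.

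edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 170 genes in mock (165 higher, 5 lower; 160 over 2-fold) and DESeq2's Wald test 486 (428 higher, 58 lower). Without the library labelled IRE1-null mock replicate 2 the count was 355 (239 higher, 116 lower), and it was 53 without IRE1-null mock 1, 52 without WT mock 1 and 63 without WT mock 2. With replicate number as a block it was 713 (558 higher, 155 lower), and with the 4 mock libraries fitted alone 0. Gene calls for Cmpk2, Usp18 and Irf7 were lost without WT mock 1 (edgeR adjusted p = 0.06, 0.101 and 0.111) and without WT mock 2 (0.0998, 0.0538 and 0.114). Ric1 (0.273, 0.0757), Sord (0.329, 0.0883) and Fcer1g (0.228, 0.169) were also lost without each of these, Plod1 (0.233) without WT mock 1, and Cd74 (0.165) without WT mock 2, while without WT mock 1 Cd74 was 3.19. Ric1, Plod1, Sord, Cd74 and Fcer1g were not called without both replicate 4 libraries (edgeR adjusted p = 0.1, 0.0933, 0.118, 0.0938 and 0.118) or with transcripts without a match kept (0.109, 0.0801, 0.0764, 0.104 and 0.0851). With those transcripts Cmpk2, Usp18 and Irf7 were not called either (0.0546, 0.0782 and 0.0514). With no filter Sord and Cd74 (0.0695 and 0.117), with a length offset Ric1 (0.0518), and without both Candida libraries numbered 2 Sord (0.0519) were not called. Without IRE1-null mock 1 edgeR adjusted p was 0.448 for Ric1, 0.0671 for Anpep, 0.279 for Plod1, 0.527 for Sord, 0.273 for Cd74 and 0.358 for Fcer1g. In the interferon list 5 of 27 genes were called over all genes and 15 adjusted over the list alone (fry adjusted p = 0.0102), and in MHC class II 1 of 4 and 3 over the list alone (fry adjusted p = 0.00383). IRE1-XBP1 targets held 0 called genes and 1 over the list alone, Edem1, and the list lost its call without WT mock 1 (0.109) or IRE1-null mock 1 (0.0512). With the block ATF6-type chaperones were lower and PERK-ATF4 genes higher (adjusted p = 0.0403 each, against 0.19 each without it). Unblocked, they had adjusted p = 0.682 and adjusted p = 0.844 with an estimated correlation. The other lists were not called (camera adjusted p 0.149 to 0.961). The self-test for this comparison recovered 7% of 2-fold and 63% of 4-fold changes.

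Under Candida the genotypes differed in 1527 genes, in which line and loss of IRE1 cannot be told apart. Interferon genes were the one list called as a group. Of its 27 members 20 were called higher (25 adjusted over the list alone, median 3.41, camera adjusted p = 4.70e-20; adjusted p = 0.243 with an estimated correlation). Oas1a was 23.1 ± 2.25 CPM in WT and 125 ± 25.6 CPM in IRE1-null cells (n = 4 and n = 4, log2 fold change 2.44, SE 0.18, edgeR adjusted p = 1.23e-05). Irf7 was 1.58 ± 0.895 and 37.4 ± 14.3 CPM (4.57, edgeR adjusted p = 7.15e-05), and Irf9, a subunit of the interferon-activated factor ISGF3, was 5.88 ± 1.54 and 34.2 ± 10.6 CPM (2.54, edgeR adjusted p = 0.000202). Usp18 was 0.0554 ± 0.0841 and 20.2 ± 9.80 CPM (edgeR adjusted p = 0.000112). Among genes with 0 counts in WT Candida were Pmepa1, a TGF-beta feedback gene on chromosome 2 (at least 560-fold higher, 20.7 ± 13.6 CPM, edgeR adjusted p = 0.0013), Tmem37 (at least 483-fold, 17.8 ± 4.92 CPM, edgeR adjusted p = 5.56e-05) and the cell-cycle inhibitor locus Cdkn2a (at least 430-fold, 15.9 ± 3.48 CPM, edgeR adjusted p = 0.000102). Among genes with 0 counts in IRE1-null Candida were Kctd17, a ubiquitin-ligase adaptor (at least 3410-fold lower, 124 ± 10.7 CPM in WT, edgeR adjusted p = 0.00233), Stag3, a meiotic cohesin (at least 941-fold lower, 34.1 ± 4.01 CPM, edgeR adjusted p = 0.00276), and Rasal3, a Ras regulator (at least 900-fold lower, 32.6 ± 7.78 CPM, edgeR adjusted p = 0.00285). With replicate number as a block these 3 had edgeR adjusted p = 0.13, 0.081 and 0.115. Unfolded-protein-response lists were not called by camera. IRE1-XBP1 targets held 1 higher and 2 lower genes (adjusted p = 0.154): Edem1 was 172 ± 23.5 and 381 ± 39.7 CPM (1.14, SE 0.14, edgeR adjusted p = 0.000322). Its relative Edem2 on chromosome 2 fell (125 ± 5.92 and 78.3 ± 5.01 CPM, -0.68, edgeR adjusted p = 0.00137), and the ER-degradation adaptor Sel1l fell (-0.53, edgeR adjusted p = 0.0195; lost without WT Candida 3, 0.0605, or IRE1-null Candida 4, 0.0557). RIDD substrates, the mRNAs cleaved directly by IRE1, held 1 higher and 2 lower genes (3 and 2 over the list alone; adjusted p = 0.721), with a median of 0.44 but a mean of -0.73. Among them the scavenger receptor gene Scara3 was at least 30.7-fold lower (edgeR adjusted p = 0.00894), the peptide-loading factor Tapbp was higher (0.59, edgeR adjusted p = 0.011). Bloc1s1, a lysosome-positioning gene, was 25.4 ± 1.76 and 34.4 ± 4.79 CPM (0.44, edgeR adjusted p = 0.0717, or 0.0246 with the block). PERK-ATF4 genes held 3 higher and 0 lower (adjusted p = 0.0713, or 0.0159 with the block; unblocked, adjusted p = 0.858 with an estimated correlation), among them Ddit3, a pro-death factor (0.72, edgeR adjusted p = 0.0234; 0.0519 to 0.081 without WT Candida 1, 2 or 3 or IRE1-null Candida 3 or 4). ATF6-type chaperones held 0 (adjusted p = 0.976).

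**Figure D3:**
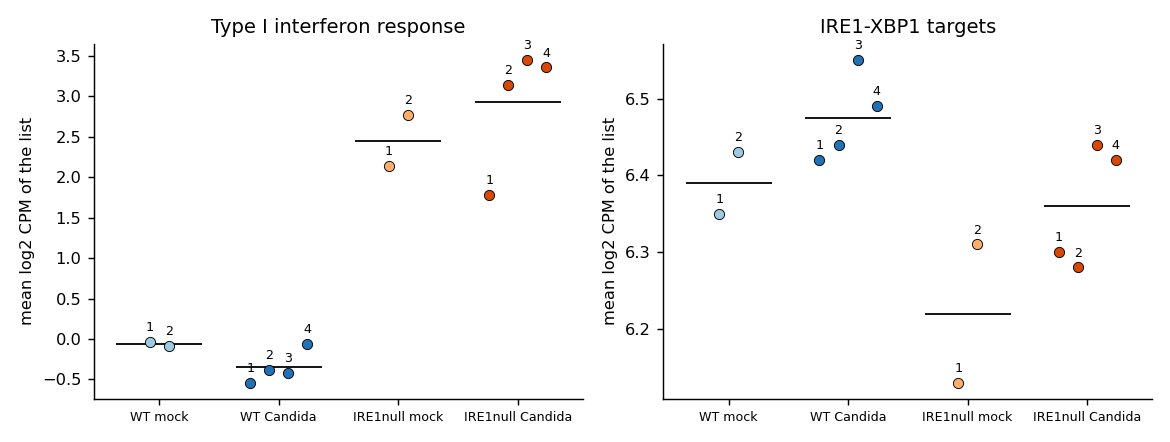
Mean log2 CPM of the members of selected gene lists (y axis of each panel) in each library (points, numbered by replicate) of the 4 groups (x axis). Type I interferon genes stand higher in IRE1-null libraries, with a median log2 fold change of 3.41 under Candida.

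Of the other immune and phagocytic lists under Candida, none was called by camera. Single members were, as were 1527 of 13410 genes over all, so called members alone do not mark a list. Cytokines and chemokines held 3 higher and 1 lower genes (camera adjusted p = 0.108): Cxcl10 was 1.10 ± 0.644 and 34.5 ± 16.9 CPM (n = 4 and n = 4, log2 fold change 4.97, edgeR adjusted p = 0.000237). Tnf (1.48, edgeR adjusted p = 0.293, or 0.0403 with replicate number as a block), Il1b on chromosome 2 (-1.26, edgeR adjusted p = 0.546) and Cxcl2 (0.96, edgeR adjusted p = 0.736) did not pass. NF-kB genes held 1 higher and 1 lower (adjusted p = 0.824), the inhibitor Tnip3 (4.63, edgeR adjusted p = 0.00754) and the co-activator Bcl3 (-1.97, edgeR adjusted p = 0.00327). Immediate early genes held 2 and 1 (0.167), among them Klf4, a macrophage-polarising factor (1.71, edgeR adjusted p = 0.00422), and the orphan receptor gene Nr4a1 (-1.83, edgeR adjusted p = 0.00818). Fungal recognition held 3 higher and 2 lower (4 and 4 over the list alone; adjusted p = 0.721): Fcer1g was 223 ± 28.7 and 497 ± 81.6 CPM (1.15, edgeR adjusted p = 0.000325). The mannose receptor gene Mrc1 on chromosome 2 was 33.5 ± 18.7 and 1.42 ± 0.835 CPM (-4.55, edgeR adjusted p = 0.00637). NADPH oxidase genes held 3 higher (adjusted p = 0.105), with the cytosolic subunit Ncf4 at 99.6 ± 11.7 and 170 ± 16.3 CPM (0.77, edgeR adjusted p = 0.00158). The 4 tested of 7 MHC class II genes held 2 higher (3 and 1 over the list alone; adjusted p = 0.0825), with Cd74 at 67.5 ± 19.2 and 456 ± 101 CPM (2.75, edgeR adjusted p = 0.000324). The class II chain gene H2-Eb1 was 0.817 CPM in IRE1-null Candida. Lysosome and phagosome genes held 4 higher and 4 lower (5 and 6 over the list alone; adjusted p = 0.78). Macrophage identity held 3 higher and 1 lower (adjusted p = 0.538), with the growth-factor receptor Csf1r (0.71, edgeR adjusted p = 0.00132) and the fractalkine receptor Cx3cr1 (4.93, edgeR adjusted p = 0.00343) higher.

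Metabolic and growth lists were not called by camera, while single members were, as were 1527 of 13410 genes over all. NRF2 genes held 1 higher and 3 lower (camera adjusted p = 0.721), with the autophagy adaptor Sqstm1 at 556 ± 85.9 and 1044 ± 120 CPM (n = 4 and n = 4, log2 fold change 0.91, edgeR adjusted p = 0.000958). LXR targets held 3 lower of 8 (adjusted p = 0.168): the receptor gene Nr1h3 on chromosome 2 was 15.7 ± 0.241 and 1.44 ± 0.969 CPM (-3.46, edgeR adjusted p = 0.00188), and the lipid carrier Apoe 60.9 ± 28.7 and 7.14 ± 2.0 CPM (-3.09, edgeR adjusted p = 0.00637). Glycolysis held 1 higher and 2 lower (adjusted p = 0.206), the hexokinase Hk1 (1.51, edgeR adjusted p = 0.00148) and the lactate exporter Slc16a3 (-2.76, edgeR adjusted p = 0.00197) among them. Inflammasome and cell death held 2 higher and 1 lower (adjusted p = 0.721), p53 targets 2 higher (0.105, or 0.0453 with replicate number as a block; unblocked, adjusted p = 0.337 with an estimated correlation), S phase 2 higher and 3 lower (0.422), G2/M 1 and 1 (1 and 2 over the list alone; 0.228) and fibroblast genes 1 lower (0.105). Cholesterol synthesis (0.538), neutrophil (0.413), dendritic cell (0.413), lymphocyte (0.413) and ribosomal protein genes (0.538) held 0, with 1 lower gene over the list alone for neutrophil and for dendritic cell. No mitochondrial transcript was listed.

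edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 1527 of 13410 genes under Candida (832 higher, 695 lower; 877 over 2-fold) and DESeq2's Wald test 2027. With replicate number as a block the count was 3135 (1640 higher, 1495 lower), and without both replicate 4 libraries 672 (395 higher, 277 lower). Without those libraries Mrc1, Nr4a1, Tnip3, Apoe, Scara3, Tapbp, Ddit3 and Sel1l were not called (edgeR adjusted p = 0.0579, 0.0555, 0.0525, 0.051, 0.0582, 0.0931, 0.105 and 0.12). Without both Candida libraries numbered 2 Sel1l, Ddit3 and Apoe were not called (0.0847, 0.101 and 0.0508) and Tnf was (0.041), and with no filter Rasal3, Ddit3 and Tnip3 were not called (0.0501, 0.0777 and 0.0536). Leaving out single libraries gave 1069 to 1447 genes. Without WT Candida 3 Usp18 was 9.78 against 8.25, and without WT Candida 1 Cx3cr1 was 5.97. fry called 6 lists: interferon and MHC class II (adjusted p = 0.000295 each), NADPH oxidase (0.00169) and p53 targets (0.00312) higher, and LXR targets (0.00169) and fibroblast genes (0.00683) lower. Differences were alike in mock and Candida: across 13410 genes the genotype differences correlated at r = 0.613, though genes are not independent replicates. Of the 165 genes higher in mock, which draw on the library labelled IRE1-null mock replicate 2, 156 were called higher under Candida (10.2 expected from independent calls), and of 5 lower 4 were (0.3 expected). The self-test for this comparison recovered 32% of 2-fold and 89% of 4-fold changes.

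Part of the genotype difference followed chromosomes (GRCm38.p6 positions). Of 839 genes on chromosome 2, 86.8% were lower in IRE1-null Candida libraries (median difference -0.48 ± 0.08 over n = 4 same-number pairs), and of genes on chromosome 13 89.3% were higher (0.52 ± 0.03, n = 4). In the mock pairs chromosome 2 stood at -0.43 and -0.23 and chromosome 13 at 0.47 and 0.19, the second of each pair using the library labelled IRE1-null mock replicate 2. Chromosome 2 holds Edem2, Nr1h3, Mrc1, Pmepa1, Sord, Hspa5, Il1b, Bcl2l11 and Pfkfb3. Chromosome 2 held 242 lower calls, 39% of the 621 lower calls at this expression level and 8.2% of genes, and chromosome 13 held 95 higher calls, 14% of 678 and 3.7% of genes. Chromosome 1 held 108 higher calls, 15.9% of 678 and 5.7% of genes. That chromosome, with Tmem37, Fcer1g and Atf3, stood at 0.29 ± 0.06 (n = 4) under Candida and at 0.35 and 0.11 in the mock pairs, the second using the library labelled IRE1-null mock replicate 2. Its first and second parts in gene order stood at 0.02 and 0.57 under Candida. The 17 other chromosomes stood at -0.08 to 0.02. Ern1 is on chromosome 11.

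**Figure D4:**
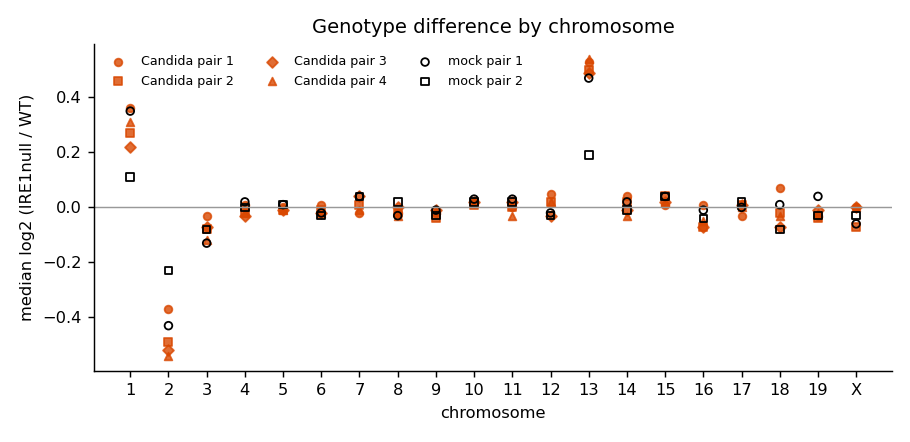
Median log2 difference between IRE1-null and WT libraries over the genes of each chromosome (x axis, GRCm38.p6), with each same-number pair as a point (y axis). Chromosome 2 is at -0.48 and chromosome 13 at 0.52 in the mean of the 4 Candida pairs.

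Whether the response to Candida itself depends on genotype was tested by the interaction, and no gene passed. Xaf1, an interferon-induced cell-death gene, had an interaction of 2.82 and Irf9 of 1.02, IRE1-null response minus WT response, both with edgeR adjusted p = 1. Ern1 (0.56), Xbp1 (0.06), Dnajb9 (0.14), Hspa5 (0.16), Tnf (-0.49), Il1b (-0.07) and Cxcl2 (-2.44) also had edgeR adjusted p = 1. The interferon list was the one list called, higher in the IRE1-null response (20 of 27 positive, median 0.78, camera adjusted p = 4.25e-05; adjusted p = 0.927 with an estimated correlation), with 0 genes called. It lost the call without WT mock 1 or IRE1-null mock 1. Its direction draws on the library labelled IRE1-null mock replicate 2, and stayed higher without that library, where the only IRE1-null mock library is from run 1. Within run 1 interferon genes went by -0.50 in WT and -0.36 in IRE1-null cells, and within run 2 by -0.29 and, against the library labelled IRE1-null mock replicate 2, by 0.37. IRE1-XBP1 targets (0.5), ATF6-type chaperones (0.133, or higher at 0.0183 with replicate number as a block; unblocked, adjusted p = 0.927 with an estimated correlation) and the remaining lists (to 0.931) were not called. edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 genes (328 at unadjusted p under 0.05, with 670 expected by chance) and DESeq2's Wald test 14 (1 higher, 13 lower). Leaving out IRE1-null mock 1 gave 38 genes, WT mock 1 2 and WT mock 2 3. The gene counts of the interaction draw on the library labelled IRE1-null mock replicate 2 as well. The self-test for the interaction recovered 3% of 2-fold and 39% of 4-fold differences, so a dependence on IRE1 of that size is mostly missed. The 2 responses correlated at r = 0.254 over 13410 genes (0.179 with replicate number as a block), with the same sign in 70.4%, and at r = 0.341 with the same sign in 85.1% of the 1856 genes at unadjusted p under 0.05 in either genotype. Run effects shared by the genotypes can raise r, since run 3 holds Candida libraries alone. Both figures draw on the library labelled IRE1-null mock replicate 2, and genes are not independent replicates.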

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

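The tests of the library labelled IRE1-null mock replicate 2 and of the 2 Candida libraries numbered 2 were chosen only after those results were seen, while the tests of chromosomes and of sample splits had written predictions first.

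The library labelled IRE1-null mock replicate 2 lies between the genotypes on 522 genes. Its median gene is 46.8% of the way from the IRE1-null to the WT library of the same run, with genes higher in WT at 47.9% and genes higher in IRE1-null cells at 46.3%. A WT library under a wrong label is argued against by this median of 46.8% and the upper quartile of 55.3%, where values near 100% would be seen. WT Candida 2 had a median of 99.3% and an upper quartile of 104.5%. RNA, cells or reads of both lines in 1 library may account for the common share of 46.8%, and at which step they would have met stays open. No biological explanation was tested.

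The 2 Candida libraries numbered 2 hold inflammatory genes at the mock level. All IRE1-null values in this paragraph draw on the library labelled IRE1-null mock replicate 2, which lies between the genotypes. An exchange with the mock libraries of that run is argued against by mock library 2 minus mock library 1 at 0.08 (WT) and -0.1 (IRE1-null), and a shift of the whole run by a ratio of mock shift to Candida shift of -0.07 (WT) and 0.08 (IRE1-null). Weak infection and mock RNA under a Candida label cannot be told apart by the difference to mock of -0.11 (WT) and 0.05 (IRE1-null), and fungal reads are not analysed here. Either may account for the value of -0.11, and the calls gained without these libraries do not tell, since the libraries were chosen by their response. No biological explanation was tested.

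Genotype differences follow chromosomes 2 and 13, for which the tests were written, and the second part of chromosome 1 in gene order (0.57, against 0.02 for the first part). A few strongly changed genes are argued against by 86.8% of chromosome 2 genes being lower, though a median below 0 already fixes that most are lower. GC content and gene length are argued against by a median of -0.46 once both trends are removed. Both parts of chromosomes 2 and 13 in gene order moved alike, the one nearest 0 by -0.48, which may reflect a copy number difference between the lines. Such a difference would lie between the lines, and no test here parts the lines from loss of IRE1. Small calls on these chromosomes, such as Edem2 (-0.68) and Fcer1g on chromosome 1 (1.15), stay open. Nr1h3 (-3.46) and Mrc1 (-4.55) lie far beyond the shift, yet line and IRE1 loss cannot be told apart for them either. Loss of IRE1 as a cause was not tested.

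Chance as the source of the 1527 genotype calls under Candida was tested only by splits. Of 35 splits of the 8 Candida libraries into 4 and 4, 1, the real one, called as many. The highest other called 82, run 3 against runs 1 and 2. Every other split puts libraries of both lines in each group, which widens the spread, so low counts there were built in. The 8 splits that part all 4 pairs include the real one, and the highest other of them called 0. With numbers read as pairs, 1 of 8 splits is the smallest share possible and too large to exclude chance, so these splits cannot decide. Apart from the splits, 156 of the 165 genes higher in mock were called higher under Candida, in other libraries (10.2 expected from independent calls). That argues against chance for these genes, though both tests share their estimate of spread and the mock calls draw on the library labelled IRE1-null mock replicate 2.

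A library far from the other 3 of its group, by the gap over the range, was seen in 18 of 192 groups tested, where chance gives about 1 in 20, or 9.6, if groups are independent. They are not, since they share libraries and hold genes that move together, so 9.6 is only a rough guide. A group with 0 in the other 3 libraries passes by construction, as for spliced Xbp1 and Ptgr1 below. Of these, 9 were libraries numbered 2. Spliced Xbp1 was 0.28% in IRE1-null Candida 4 (0% in the others). Atf4 was 151.4 CPM in WT Candida 2 (404.5 to 455.5), and Mthfd2 81.71 CPM there (143.1 to 155.3). Bloc1s1 was 28.04 CPM in WT Candida 2 (24.26 to 24.69) and 41.58 CPM in IRE1-null Candida 2 (31.48 to 32.61). In IRE1-null Candida 2 Csf1r was 1710 CPM (1626 to 1636), Edem1 322 CPM (398.1 to 406.5) and Sqstm1 865.1 CPM (1086 to 1113). Irf7 was 2.913 CPM (1.021 to 1.294), Irf9 8.168 CPM (4.84 to 5.337) and Stag3 28.1 CPM (35.39 to 36.77) in WT Candida 1. Oas1a was 87.35 CPM (135 to 142.9) in IRE1-null Candida 1. Ptgr1 was 0.2637 CPM in WT Candida 2 (0 in the others). Of list means in log2 CPM, lysosome and phagosome was 7.72 in WT Candida 1 (8.08 to 8.14), NADPH oxidase 8.14 (8.43 to 8.44) and S phase 7.05 (6.54 to 6.62) in IRE1-null Candida 1, LXR targets 4.72 in IRE1-null Candida 2 (4.36 to 4.42), and the 1 tested neutrophil gene -2.35 in IRE1-null Candida 3 (-0.88 to -0.6).

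A difference between the genotypes in the response to Candida was called for the type I interferon list (camera adjusted p = 4.251e-05 for the interaction, and 0.927 with an estimated correlation). The call was lost without WT mock 1 or IRE1-null mock 1. It draws on the library labelled IRE1-null mock replicate 2, and its direction was the same without that library.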

How the results depend on the processing

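Tests without the Candida libraries numbered 2, alone or with the library labelled IRE1-null mock replicate 2, tests with transcripts without a match kept, those on genes at unadjusted p under 0.05 and the blocks for the correlation of responses and the spliced share were chosen only after results were seen.

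Of genes, only those named by the rule and printed were followed over the alternatives. None of these that was called, and no called list, changed direction. Some lists that were not called did, such as RIDD substrates in WT. Of results for these genes 1806 kept their side of the threshold or got no adjusted p, 62 passed it and 78 fell short. Of results for called lists 183 kept it and 85 fell short. Depth of 17.7 M to 25.9 M counts limits genes near 3 counts, and 2 mock libraries per genotype limit every comparison with mock. The cause was not tested for any count below, beyond fewer libraries in the fit.

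Genes called in WT Candida against mock (0) were 36 by the DESeq2 Wald test, 1 with no low-count filter, 200 without both Candida libraries numbered 2, 144 without these and the library labelled IRE1-null mock replicate 2, and 0 to 8 leaving out 1 library. In IRE1-null cells (0) they were 1 with DESeq2 size factors, 97 by the Wald test, 2 with no filter, 1 with a length offset, 2 with a run block, 166 and 6 without those libraries, and 0 to 69 leaving out 1 library. For the genotypes in mock (170) they were 486 by the Wald test, 77 without both replicate 4 libraries, 713 with a replicate block, 930 with a run block, 441 without the 3 libraries, 58 with transcripts without a match kept, 0 with the 2 groups alone, and 52 to 355 leaving out 1 library. For the genotypes under Candida (1527) they were 672 without both replicate 4 libraries, 3135 with a replicate block, 3447 with a run block, and 1069 to 1447 leaving out 1 library. For the interaction (0) they were 14 by the Wald test and 0 to 38 leaving out 1 library.

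Lists called with an estimated correlation, by fry and by mixed fry were 0, 0 and 0 in WT (6 by camera), 0, 1 and 1 in IRE1-null cells (8), 0, 2 and 1 for the genotypes in mock (3), 0, 6 and 16 under Candida (1), and 0, 0 and 0 for the interaction (1). With a replicate block and with a run block they were 5 and 5 in mock, 3 and 3 under Candida, and 2 and 2 for the interaction. Without both Candida libraries numbered 2 they were 6 in mock, 4 under Candida and 2 for the interaction, and with the library labelled IRE1-null mock replicate 2 also out 5 in mock and 5 under Candida. Without both replicate 4 libraries 3 were called under Candida. Leaving out 1 library gave 3 to 7 in WT, 5 to 9 in IRE1-null cells, 2 to 5 in mock, 1 to 4 under Candida and 0 to 6 for the interaction. The replicate block (3135 genes under Candida) changed no call of a list or named gene beyond those printed beside the results.

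The correlation of the 2 responses (0.254) was 0.173 without both replicate 4 libraries, 0.341 over genes at unadjusted p under 0.05, 0.319 without both Candida libraries numbered 2, 0.179 with a replicate block, 0.188 with a run block, and 0.162 to 0.288 leaving out 1 library. The called genes alone gave no value, since none was called in either genotype. The spliced Xbp1 difference (-3.86 points) was -4.15 without both replicate 4 libraries and -4.96 without both Candida libraries numbered 2 (exact permutation p = 0.1 each, the smallest possible with 3 against 3), -3.86 with a replicate block that swaps within pairs (exact permutation p = 0.125, the smallest possible for 4 pairs), and -4.98 to -2.41 leaving out 1 library.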

Other observations

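The genes in this part were chosen after their values were seen, by no test.

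A set of genes was seen in 1 line alone. Of genes with at most 3 counts over one line and above 2 CPM in every library of the other, the library labelled IRE1-null mock replicate 2 set aside, 17 were seen in IRE1-null cells, among them Cdkn2a, Tmem37, Pmepa1, Aldh1l1 and the homeobox gene Hoxa7, and 9 in WT cells, among them Kctd17, Stag3, Rasal3, the anticoagulant Pros1 and the prostaglandin receptor Ptger3. Cdkn2a had 0 counts in all 6 WT libraries and 16.83 ± 3.59 CPM on library totals alone in 5 IRE1-null libraries, with 8.18 CPM in the library labelled IRE1-null mock replicate 2. Its neighbour Cdkn2b, a second cell-cycle inhibitor on chromosome 4, had 0 counts in WT and 3.36 ± 1.11 CPM in those 5 libraries. Mtap, a methionine-salvage gene beside them, was 91.29 ± 14.52 CPM in WT and 88.16 ± 19.55 CPM in IRE1-null libraries. Kctd17 was 110 to 136 CPM in WT Candida libraries, 0 in IRE1-null Candida libraries, and 0.063 and 53.7 CPM in IRE1-null mock, the second in the library labelled IRE1-null mock replicate 2.

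The cytokine genes Il6 and Il10 gave little signal at 4 h. Il6 had 0 counts in all 12 libraries, and Il10 was 0 to 0.259 CPM, below the filter. Ifit2 had 0 counts in all 8 Candida libraries of both genotypes and 0.713 and 0.528 CPM in WT mock.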
